A study of Homo sapiens with 4 samples.

How the data were processed

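CUT&Tag profiles were measured in 22RV1, a human prostate cancer cell line, in 4 libraries: cells given the CDK4/6 inhibitor PD0332991 (palbociclib), the control of the inhibitor, cells given a control siRNA, and cells given an siRNA against RB. Each group held 1 library, so no difference had a replicate check and no p-value was computed between groups. The antibody target was not given in the sources used here, and the labels' protocols describe fixed and sonicated chromatin with input and precipitated material.

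Reads were converted with bcl2fastq 2.17, trimmed with Trimmomatic 0.33, aligned with Bowtie2 (version given as 2) to hg38, and intervals were called with MACS2 2.1.0, per the submitters' processing notes, which name these tools without their order or settings. The deposited lists hold 1 library each, with 10 columns for the inhibitor pair and 9 for the siRNA pair, which lack the interval name. The deposited score is the whole part of a multiple of the −log10 p. The fold at each summit is the authors' ratio of treatment to background, and the deposited −log10 p and −log10 q belong to the same summit. The score, fold, p and q are the authors' values for each interval and were used to describe, rank or filter within a list. The lowest deposited −log10 p was above the value of a p of 0.05 in every list, and no q threshold was visible.

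The fold and p of each deposited summit were solved for the background level and the number of treatment fragments, with the MACS2 pseudocount of 1 and its Poisson upper tail. The solved numbers were whole within 0.05 for 100% of summits in each list. The solution chooses among background levels, which favours whole numbers, so the check was repeated on the summits at the genome-wide background, where no choice is made: 100% of 9159, 3180, 9907 and 2566 summits (inhibitor control, inhibitor, siRNA control, RB siRNA) were whole, against 10% by chance. Steps in the local background gave the fragment length under an assumed large window of 10000 bp, and an assumed effective genome size of 2.7 Gb gave library totals. The totals depend on these assumed values, and ratios between libraries do not depend on the genome size. On lists simulated with known counts, 100%, 99.97%, 100% and 100% of counts were recovered.

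Recovered fragments at a summit were scaled to 1000000 treatment fragments in their library (FPM). This measure was chosen after seeing the data, because the intervals tile the genome and overlap carries almost no information. Summits of a pair of libraries were matched when each was the nearest of the other within 250 bp, an overlap rule fixed before the data were examined. Pairs with a geometric mean of at least 5 FPM were kept, a minimum chosen after seeing the data. The log2 ratio of each pair carries an exact conditional 95% interval, and a summit was called beyond counting error when that interval excluded the median ratio of its comparison. Such calls compare 2 libraries, not conditions. In simulated pairs, 72% of 2-fold and 94% of 4-fold changes were called for the inhibitor, against 3.70% of unchanged summits. For RB siRNA the values were 69%, 94% and 2.44%. The simulated pairs had equal depth and all stayed shared. In the data a lowered summit can be hidden by a higher one and drop out. The simulated rates therefore do not cover such losses. Intervals on shares are exact binomial (Clopper-Pearson) at 95% and cover counting error only.

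Gene positions came from RefSeq on GRCh38, the build of the lists. The table holds no strand, so a summit within 1000 bp of either end of 1 of 20033 protein-coding genes was counted as at a gene end, in place of the planned 5′ end. The 18 gene lists and the rule for named genes were fixed before the data were examined. The number of list members with a summit at a gene end was set beside 10000 random lists matched on local gene density and gene length, in place of promoter GC, and a list stood apart at or beyond the 2.5th or 97.5th percentile. With 18 lists in each library, some are expected to stand apart by chance alone. Per contrast, the rule takes the 8 gene-end summits with the highest authors' fold that are shared, control-only and treated-only, the 2 highest of each list, 11 fixed genes, and members of the gene lists. The result of 1 fixed gene is not reported here. Sharing was read from summits within 250 bp in place of overlap. The genes named for a level above or below the median shift, up to 10 per direction, were chosen after their values were seen, as were those named for a summit without a partner that stayed higher beyond counting error, those compared across all 4 libraries and the repeats on chromosome 21 and the subtelomere of chromosome 5.

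Motif searches were not run because no genome sequence was used here. Intervals on chromosomes 1 to 22, X and Y were the main set. Treated intervals and summits were placed at random 1000 times. Alternatives covered stricter q and fold, all contigs, merging, other overlap rules, equal list lengths, thinning, other windows, and, added later, other distances and minimum levels. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1.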

Results

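The series profiled chromatin of 22RV1 prostate cancer cells by CUT&Tag, to ask how inhibition of CDK4/6, the kinases that phosphorylate the retinoblastoma protein RB, and loss of RB itself alter binding in the genome. There were 4 libraries, with 1 per group: the CDK4/6 inhibitor PD0332991, its control, an siRNA against RB, and its control. Recovered treatment fragments numbered 2458795 in the inhibitor control, 1909232 under the inhibitor, 3479939 in the siRNA control and 2423492 after RB siRNA. Levels are given in FPM, the recovered fragments at a summit scaled to 1000000 fragments in the library. No difference below has a replicate check, and intervals cover counting error only.

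In all 4 libraries the summits of intermediate height lay at genes. Of summits with 5 to 50 FPM, 64.6% (95% interval 62.5 to 66.7, n = 2059) were at the end of a protein-coding gene in the inhibitor control, 63.2% (60.5 to 65.9, n = 1280) under the inhibitor, 66.5% (64.1 to 68.8, n = 1647) in the siRNA control and 64.7% (61.7 to 67.6, n = 1034) after RB siRNA. Random positions fell there in 2.52%, 2.48%, 2.45% and 2.56% of cases. Over all deposited summits the shares were 29.3%, 40.2%, 28.4% and 43.4%. The highest summit in every library lay at the end of CIMAP1D on chromosome 19 (position 491914 in both controls, hg38), with 2224 FPM in the inhibitor control, 2882 under the inhibitor, 1077 in the siRNA control and 2007 after RB siRNA. The next highest authors' fold was at HCN2 in the inhibitor control (21.3), at FARP2 under the inhibitor (12), and in the ribosomal RNA repeats of chromosome 21 in the siRNA control (24.8) and after RB siRNA (9.47).

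**Figure D1:**
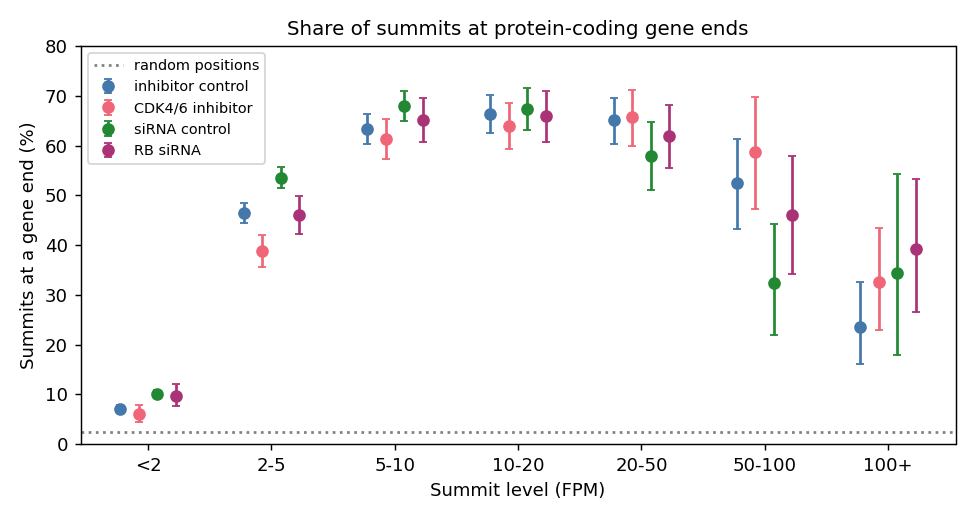
Percentage of summits within 1000 bp of either end of a protein-coding gene (y axis) by summit level in FPM (x axis) in each of 4 libraries; points are shares, bars exact 95% binomial intervals, and the dotted line random positions. Shares were highest between 5 and 50 FPM and were 23.6% to 39.3% at 100 or more.

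Genes of the p53 response and immediate early genes carried summits within 1000 bp of their ends more often than matched random lists in each of the 4 libraries. For the 23 p53 targets, 10 members had a summit in the inhibitor control (3.68 in random lists, percentile 99.9), 5 under the inhibitor (1.66, percentile 98.7), 11 in the siRNA control (3.73, percentile 99.995) and 5 after RB siRNA (1.42, percentile 99.4). RRM2B, a ribonucleotide reductase subunit induced by p53, had 43.5, 57.6, 31.0 and 45.4 FPM in the same order, and TP53I3, whose end is shared with SF3B6 and FAM228B, had 55.7, 72.8, 37.1 and 43.3. Of the 23 immediate early genes, 8, 6, 12 and 4 had a summit (percentiles 99.4, 99.9, 100 and 97.6). The transcription factor gene EGR1 had 28.5, 27.8, 14.9 and 21.9 FPM, and the phosphatase gene DUSP1 11.8, 10.5, 6.90 and 14.0. In the treated libraries these calls depended on the setting. Under the inhibitor p53 targets did not stand apart with a window of 500 bp (percentile 97.0) or with gene bodies and 5000 bp on each side (94.6). After RB siRNA p53 targets did not at 500 bp (91.9), nor did immediate early genes at 500 bp (93.8), at 2500 bp (95.9) or against unmatched lists (96.3). DNA repair genes stood apart in the controls, with 11 of 27 (percentile 99.5) and 13 of 27 (percentile 99.96), and not under the inhibitor (3, percentile 67.9) or after RB siRNA (3, percentile 74.9), a difference that was not tested. With gene bodies and 5000 bp on each side the controls gave percentiles of 88.1 and 94.3. Among all protein-coding genes, 3371 and 3465 had a gene-end summit in the controls, 1548 under the inhibitor and 1328 after RB siRNA. Lower counts of list members in the treated libraries are therefore not shown to be a loss at those genes. Cytosolic ribosomal protein genes stood apart in the inhibitor control, with 17 of 85 (percentile 97.8), but not against unmatched lists (78.6), at 2500 bp (93.8) or among summits of at least 5 FPM (16.8). Markers of blood, endothelial and liver cells had 0 of 24 there (percentile 0.92, and 5.68 among summits of at least 5 FPM).

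E2F targets and reported ETS1 targets did not stand apart in any library. E2F targets of G1/S and replication had summits at 9 of 37 members in the inhibitor control (percentile 85.0), 2 under the inhibitor (29.2), 6 in the siRNA control (40.7) and 3 after RB siRNA (62.1). Reported ETS1 targets had 3, 2, 3 and 2 of 28 (percentiles 17.2, 45.9, 15.6 and 53.1). Neither list stood apart under any other window, matching or minimum level tried. The list of D-type cyclins, CDKs, CDK inhibitors and the RB family had 3 of 22 members with a summit after RB siRNA (percentile 88.3), and 7 (percentile 99.7) with gene bodies and 5000 bp on each side. Among fixed genes, CDK4 had a summit at its end with 42.3 FPM in the inhibitor control, 30.2 in the siRNA control and 35.9 after RB siRNA. CCND1, which encodes cyclin D1, had 11.8, 5.46 and 7.84 in those libraries, and CCNE1 had 9.76 in the inhibitor control and 6.60 after RB siRNA. MYC had 2.1 under the inhibitor and 2.01 in the siRNA control. No library had a listed summit at an end of RB1, ETS1, KLK3, CDK6, CDKN1A or E2F1. Each interval lists 1 summit, so a lower one at a gene end would be hidden. The interval over E2F1 had its summit elsewhere, with 13.4 FPM in the inhibitor control. Under the inhibitor it had 136 FPM, in the siRNA control 57.5 and after RB siRNA 90.4. These last values equal those of the summit at RALY, another gene of chromosome 20, and are not levels at E2F1. The interval over KLK3 had 50.4 FPM in the inhibitor control. Under the inhibitor, the highest summit in intervals over CDK4 had 32.5 FPM, and over CCND1 28.3. The deposited lists hold no measure of RB level, so the knockdown was not checked.

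The lists of treated cells held fewer intervals than those of their controls. The inhibitor list had 3206 intervals against 9720 in its control, and the RB siRNA list 2553 against 10412. The intervals covered 3.05, 3.03, 3.06 and 3.03 Gb in that order, with median widths of 557, 189, 718 and 180 kb. At the genome-wide background a position with 0 fragments has a −log10 p of 3.19, 2.61, 3.24 and 2.63, above the threshold of the lists. Background read ends recovered from the lists numbered 9591, 34562, 7641 and 36253, and intervals per 1000 of them were 334, 281, 334 and 287. Per 1000 treatment fragments the values were 1.68, 3.95, 1.05 and 2.99. At a −log10 q of at least 5 the lists held 18, 105, 7 and 42 intervals. At the genome-wide background 1 treatment fragment added about 0.005, 0.014, 0.003 and 0.010 to the fold. A fixed fold or q thus needs more fragments in the treated lists, and these counts do not measure loss. Summits of at least 100 FPM numbered 89, 110, 56 and 29.

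**Figure D2:**
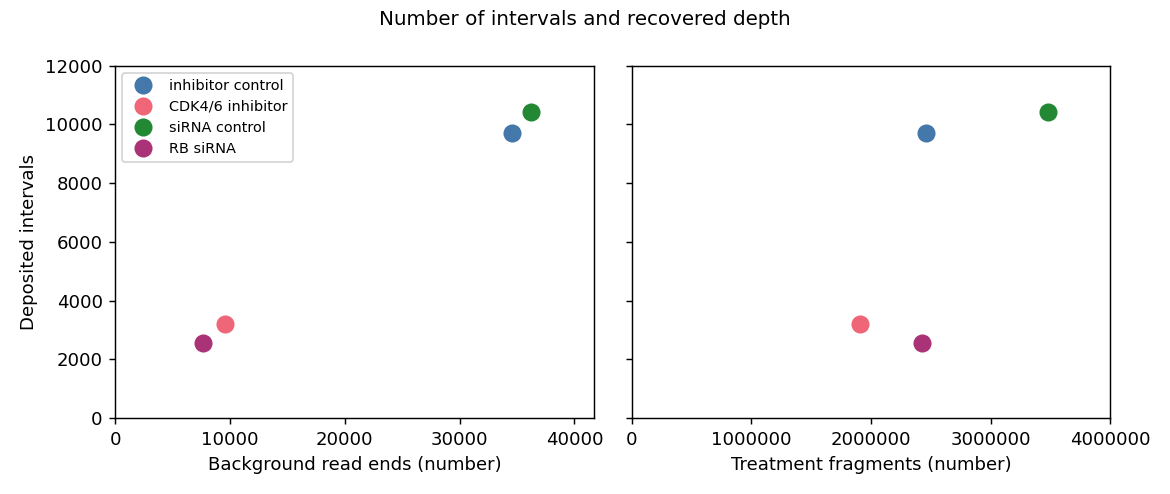
Number of deposited intervals per library (y axis) against the number of recovered background read ends (left) and of treatment fragments (right), 1 point per library. The libraries with 9591 and 7641 background read ends had the fewest intervals.

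Under the CDK4/6 inhibitor, gene-end summits differed from the control in both directions. Relative to the median shift, the summit at WDR91, which acts in endosome maturation, was higher under the inhibitor, with 18.9 against 3.66 FPM (log2 ratio 2.36, 95% interval 1.28 to 3.60). So were those at RNPC3, of the minor spliceosome (2.1, 1.14 to 3.17), at RAD21, a cohesin subunit (1.81, 0.49 to 3.30), at the pseudokinase gene TRIB1 (1.09, 0.72 to 1.47) and at TMEM87B (1.10, 0.95 to 1.26). Lower summits lay at MXD3, a MAX partner, with 15.2 against 31.7 FPM (log2 ratio -1.06, -1.73 to -0.43), at LMNB1, which encodes lamin B1 (-1.14, -2.22 to -0.15), at RALA, a small GTPase gene (-1.39, -2.74 to -0.21), at TMEM39B (-1.26, -2.28 to -0.32) and at ZBTB5 (-1.03, -1.88 to -0.24).

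Across the 887 summits shared by the inhibitor and its control with at least 5 FPM, 603 of them at gene ends, the median log2 ratio was 0.20 (0.17 to 0.24). Of these summits 81 lay above and 69 below the median shift beyond counting error, 16.9% in all (14.5 to 19.5), and at gene ends the counts were 43 and 34. Among summits of at least 20 FPM the share was 27.9%. Intervals under the inhibitor were wider (median 557 against 189 kb), and each lists only its highest summit. Sharing may thus favour summits that are high under the inhibitor, which was not tested. The shared summits with the highest fold included WDR27 (log2 ratio 0.44, 0.33 to 0.55), MUC8 (0.02, -0.11 to 0.15), BRD3OS (0.34, 0.21 to 0.47), the caspase gene CASP9 (0.27, 0.09 to 0.45) and LOC124900172, the 1 of the 8 named by the rule that was lower under the inhibitor (-0.53, -0.75 to -0.31). Among the gene lists, replication-dependent histones had 4 shared members at 2 summits. The summit of H2AC11 and H2BC11 lay below the shift, with 18.3 FPM in the control and 12 under the inhibitor, and that of H2AC18 and H3C14 lay within counting error (31.3 and 28.3). Immediate early genes and p53 targets had 4 shared members each and none beyond counting error. KRAB-type and other ZNF-numbered genes had 1 of 12 above (median percentile 92.5 among matched lists). Oxidative phosphorylation genes had a matching summit under the inhibitor for 1 of 17 control summits, at percentile 2.35 of lists matched on fold, and epithelial-mesenchymal transition genes for 2 of 3 (percentile 97.9). For oxidative phosphorylation genes the values were 5 of 17 after RB siRNA (percentile 75.7) and 7 of 17 between the controls (45.2). For epithelial-mesenchymal transition genes they were 0 of 3 (28.3) and 1 of 3 (47.3). Between the controls, ZNF-numbered genes had a match for 25 of 74 (percentile 1.29) and neuroendocrine genes for 3 of 3 (97.7). A summit hidden by a higher one counts as unmatched, so these counts do not measure loss. With 18 lists per comparison, some such percentiles are also expected by chance alone.

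Most control summits without a partner under the inhibitor were hidden by a higher one. Of 2295 control summits with at least 5 FPM, 839 had a partner under the inhibitor and 1456 did not. Among the latter, 1191 lay in a treated interval whose own single summit was as high or higher, so a lower one would not be listed. For 16 the treated interval stayed lower beyond counting error, among them the gene ends of SPTSSB (9.35 against at most 1.57 FPM), FZD4 (11.8 against at most 5.24) and E2F8, an atypical E2F repressor gene (6.51 against at most 2.1). In the other direction, of 512 inhibitor summits without a partner among 1449, 183 were hidden and 194 had a lower control interval, 30 of them beyond counting error, including TARS3 (21.0 against at most 5.29), ZNF592 (34.0 against at most 15.5) and MNT, a MAX partner (96.4 against at most 63.0). The control summits without a partner that had the highest fold lay at HYAL1, HYAL3 and NAA80 (fold 6.15), SPATC1L (6.09) and PPP2R5C (5.77). The inhibitor interval over HYAL1, HYAL3 and NAA80 held a higher summit (189 against 156 FPM), the inhibitor summit at PPP2R5C lay outside the matching distance (125 against 144 FPM), and SPATC1L lay in a gap of the inhibitor list. The highest fold under the inhibitor without a partner was at FARP2 (1148 FPM), in a gap of the control list.

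After RB siRNA, most shared summits were higher in FPM than in the siRNA control, at genes and elsewhere alike. The summit at RAB22A, a small GTPase gene of endosomes, had 27.6 against 5.46 FPM (log2 ratio 2.34, 1.59 to 3.16). Others above the median shift were CCN1, a matricellular protein gene (1.87, 0.90 to 2.92), PRDM9, a histone methyltransferase gene (1.64, 0.90 to 2.42), OGDH, of the citric acid cycle (1.26, 0.92 to 1.62), and MUC8 (1.13, 0.94 to 1.31). DET1, of a ubiquitin ligase, was lower, with 4.13 against 8.91 (log2 ratio -1.11, -2.30 to -0.04). ABI1 (-0.69, -1.63 to 0.19), the Polycomb partner gene RYBP (-0.70, -1.68 to 0.21) and the chaperone gene HSPA8 (-0.29, -0.95 to 0.35) lay below the shift with ratios whose own intervals included 0.

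The 749 summits shared by RB siRNA and its control, 502 of them at gene ends, had a median log2 ratio of 0.45 (0.42 to 0.47), and 636 were higher after RB siRNA. The medians were 0.45 at gene ends and 0.45 elsewhere. Intervals after RB siRNA were wider (median 718 against 180 kb), and each lists only its highest summit. Sharing may thus favour summits that are high after RB siRNA, and the size of this effect was not tested. Of all 749, 57 lay above and 43 below the shift beyond counting error, 13.4% (11 to 16), and at gene ends 26 and 20. Among summits of at least 20 FPM the share was 23.4%. LIG1, the DNA ligase of replication, was the 1 E2F target with a shared summit and lay above the shift, with 28.5 against 14.1 FPM. CDK4 and CCND1 were shared and within counting error, as were EGR1, DUSP1, JUNB and KLF4 of the immediate early genes (median percentile 75.4). Of 1041 control summits without a partner, 942 were hidden by a summit as high or higher, and for 2 the treated interval stayed lower beyond counting error, neither at a gene end. In the other direction, of 371 summits without a partner, 96 were hidden and 12 had a control interval that stayed lower beyond counting error, among them SMAD6, an inhibitor of BMP signalling (35.9 against at most 17.5), and CAP1 (15.7 against at most 6.61).

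By median ratio and by the share of shared summits beyond counting error, the controls of the 2 contrasts differed by more than either treated library from its control. Of the 1191 shared summits, 142 lay above and 100 below the median shift, 20.3% (18.1 to 22.7), and the median log2 ratio of the inhibitor control over the siRNA control was 0.59 (0.57 to 0.62). Among summits of at least 20 FPM, 34.9% differed beyond counting error. The 3 comparisons used different summits and depths, and the interval of the inhibitor share (14.5 to 19.5) overlaps that of the controls. Across the 446 summits shared by all 4 libraries, the standard deviation of the log2 ratio was 0.54 between the controls. It was 0.51 for the inhibitor and 0.43 for RB siRNA. MUC8 (log2 ratio 1.92, 1.75 to 2.08), FBXO33 (1.83, 1.23 to 2.46) and MXD3 (1.70, 1.10 to 2.33) were higher in the inhibitor control. ODC1, of polyamine synthesis (-1.08, -1.72 to -0.48), RYBP (-1.46, -2.70 to -0.37) and SKIL, a repressor of SMAD signalling (-1.36, -2.47 to -0.37), were higher in the siRNA control. Of the genes named above for a treated library, MXD3, MUC8, RYBP, RAB22A, OGDH, RALA, TRIB1, TMEM87B, WDR27, BRD3OS, CASP9, SPATC1L and LOC124900172 thus also differed between controls beyond counting error. RAB22A had 18.3 FPM in the inhibitor control against 5.46 in the siRNA control. RNPC3, RAD21, TMEM39B, CCN1 and WDR91 had no summit shared by the controls at 5 FPM or more. WDR91 had 3.66 FPM in the inhibitor control and 3.16 in the siRNA control. On the log2 scale this lay -0.44 from the median shift between the controls at summits shared by all 4 libraries.

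**Figure D3:**
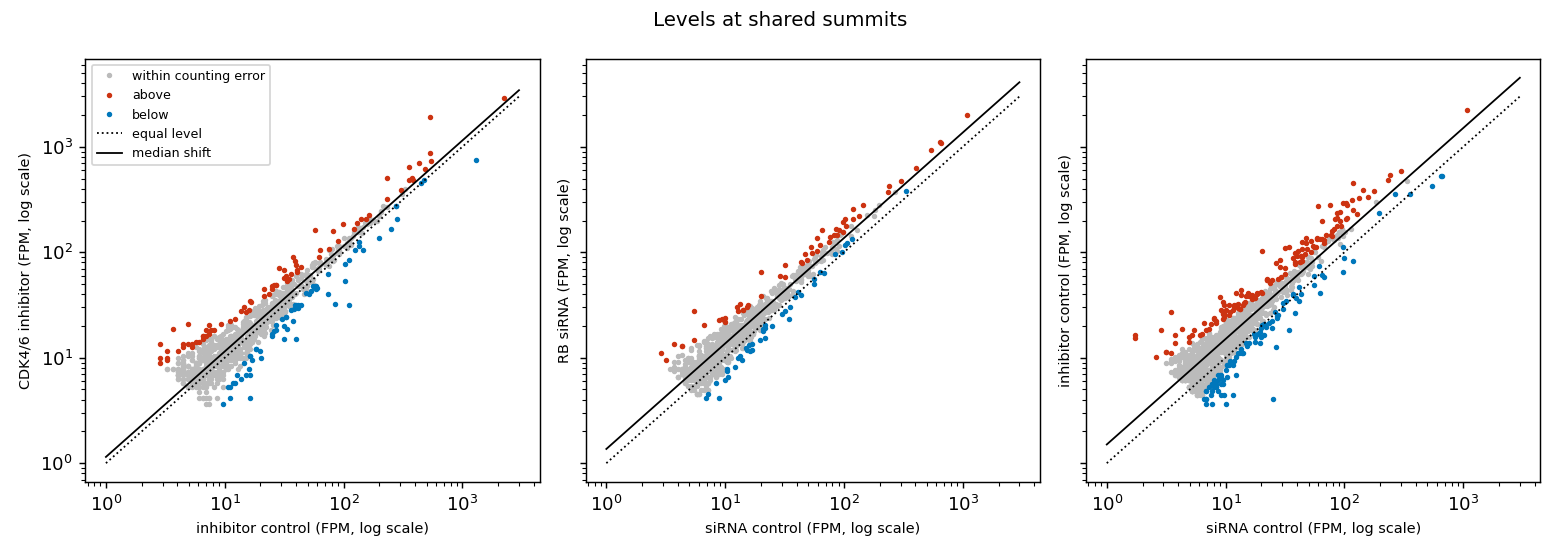
FPM at shared summits outside chromosome Y (log scales) for the inhibitor against its control, RB siRNA against its control, and the controls against each other; each point is 1 summit, coloured where its exact 95% interval excludes the median shift (solid line). The median log2 ratios are 0.20, 0.45 and 0.59.

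By overlap of at least 1 bp, almost every interval was shared. The treated lists covered 99.1% of inhibitor control intervals (98.9 to 99.3) and 99.3% of siRNA control intervals (99.1 to 99.4), against 71.2% and 69.6% for random placements. Randomly placed intervals could overlap each other and leave parts of the genome bare, whereas the deposited intervals tile it. The excess over random placements is therefore no measure of shared binding. Treated intervals absent from their control made up 0.47% (0.26 to 0.77) and 0.12% (0.024 to 0.34), or 31.7% and 34.7% with lists of equal length, and 99.7% of inhibitor control intervals overlapped the siRNA control list. In the top quartile of authors' fold, 98.1% and 99.2% were retained. Of 9687 sites in both controls, 10 were lost in both contrasts, against 0.40 for independent losses. A site lost by this rule lies in a gap of the treated list. Positions with 0 fragments pass the threshold, so such a gap does not show a loss of binding. When 0.5 of each interval had to overlap, 10.7% and 7.83% of control intervals were covered and 2160 sites were lost in both contrasts, against 2117 for independent losses. By summits within 250 bp, 907 were lost in both, against 737, or 802 within quintiles of fold. A summit hidden by a higher one in the treated list counts as lost here, so these counts do not measure shared loss. By summits within 250 bp, 12.1% and 10.5% of control summits were retained, against 0.053% and 0.043% for random placements, and in the top quartile of fold 36.0% and 33.5%.

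The contrasts were set side by side at the 307 gene-end summits shared by all 4 libraries. Values here are centred on the median shift of summits shared by all 4 libraries. WDR91 was above this shift in both contrasts, by 2.14 and 1.14 on the log2 scale, and BARD1, a BRCA1 partner gene, lay near it in both (-0.09 and -0.09). LMNB1 lay at -1.36 under the inhibitor and 0.08 after RB siRNA, MXD3 at -1.28 and 0.77, and RAB22A at -0.03 and 1.90. Across these summits, which are not independent replicates, Spearman's rho was -0.09 (bootstrap 95% interval -0.21 to 0.02) and Pearson's r -0.07, and r was -0.11 without the 2 summits farthest from the median under the inhibitor. Across all 446 summits shared by the 4 libraries rho was -0.13 (-0.22 to -0.03), and across the 116 at gene ends with at least 20 FPM it was -0.22 (-0.40 to -0.03). The contrasts have separate controls.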

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

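The tests in this part were chosen after the results were seen.

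Contigs outside the main set entered the comparisons only in the setting with all contigs. On each contig in both lists of a contrast whose highest summits had a geometric mean of at least 100 FPM, those 2 summits were compared, and 3 contigs had a ratio above the median shift. On chrUn_GL000220v1 the highest summit was 1.74 times as high in FPM under the inhibitor as in its control, and another summit of that contig (position 112303) was 1.72 times as high after RB siRNA as in its control. On chr22_KI270733v1_random the ratio was 1.95 under the inhibitor. The highest summits there after RB siRNA and in its control lay at different positions (131312 and 123205), so their ratio of 1.59 is not a change at 1 summit. On chrUn_GL000195v1 the ratio was 1.43 under the inhibitor. Each interval excluded the median shift of its comparison, and no explanation was tested.

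The lists of treated cells held fewer intervals than their controls. The number per treatment fragment differed 3.75 times between the highest and the lowest list, which argues against the depth of the treatment library as the cause. The number per background read end differed 1.19 times, consistent with the depth of the background library used by the peak caller. This remains a hypothesis, since the background library itself was not analysed here. At the genome-wide background, positions with 0 fragments pass the threshold in every list (−log10 p from 2.61 to 3.24). The number of intervals is therefore no count of bound sites, and fewer intervals do not show a loss of binding.

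Shared summits were higher in FPM after RB siRNA than in its control. The shift at gene ends minus that elsewhere was -0.0054 on the log2 scale, which argues against a response confined to gene ends. The controls, both unperturbed by RB siRNA or inhibitor, differed by a median of 0.589 on the same scale. Enrichment over background that differs from library to library is a candidate explanation. FPM was not adjusted for the recovered fragment length, which was 204 bp after RB siRNA and 174 bp in its control. It was 191 bp in the inhibitor control and 183 bp under the inhibitor, where shared summits were nevertheless higher. The part of fragment length in these shifts was not tested. Sharing may also favour summits that are high after RB siRNA, since its intervals were wider and each lists only its highest summit. A response of the whole genome to RB loss stays open, since 1 library per group confounds it with the library.

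Single gene-end summits moved beyond counting error in both contrasts. Between the 2 controls 20.3% of shared summits did so, against 16.9% and 13.4% in the contrasts. At gene ends only the shares were 15.4%, 12.9% and 9.16%, so variation between libraries of unperturbed cells could account for their number. The controls may also differ by their own treatments, and which single summits respond to a treatment stays open.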

How the results depend on the processing

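The settings on FPM, minimum levels, distances of 100 and 500 bp, gene ends only, and the top quartile of fold by summits within 250 bp were chosen after seeing the data; the others were fixed before the data were examined. No setting reversed the direction of a median ratio, and 71 values stayed the same while 80 moved; the cause was not tested unless the setting itself removes or redefines intervals. Values follow the order inhibitor control, inhibitor, siRNA control, RB siRNA where there are 4. At a −log10 q of at least 5, the lists held 105, 18, 42 and 7 intervals, the treated lists covered 26.7% and 26.2% of control intervals, 5.56% and 0% of treated intervals were absent from their control, 45.7% of inhibitor control intervals overlapped the siRNA control, and gene ends held 33.3% under the inhibitor and 33.3% in the siRNA control. At a fold of at least 5 the lists held 76, 15, 23 and 5 intervals, with 35.5% and 30.4% covered, 6.67% and 0% absent, 42.1% shared by the controls, and gene ends at 26.3% (inhibitor control), 39.1% (siRNA control) and 40% (RB siRNA). A fixed fold or q needs more fragments in the treated lists than in their controls, so the shares covered under these 2 settings do not measure loss. With all contigs, 96.7% and 97.0% were covered, 1.57% and 0.84% absent and 98.9% shared by the controls, with gene ends at 28.3% and 27.4% in the controls. With overlap of 0.5 of each interval, 10.7% and 7.83% were covered, 67.7% and 68.1% absent, 30.1% shared by the controls, and 2160 sites lost in both contrasts. With summits within 250 bp, 12.1% and 10.5% were covered (36.0% and 33.5% in the top quartile of fold), 63.3% and 57.3% absent, 21.1% shared by the controls, and 907 lost in both. With lists of equal length, 98.4% of inhibitor control intervals were covered, 31.7% and 34.7% absent, and 99.1% shared by the controls. Gene ends held 25.6%, 35.7%, 25.1% and 39.3% of summits in a window of 500 bp, 33.3%, 43.9%, 32.4% and 47.4% in one of 2500 bp, and 62.0%, 61.1%, 64.5% and 62.3% among summits of at least 5 FPM. The number of gene lists standing apart was 1 under the inhibitor and 1 after RB siRNA with 500 bp, 1 after RB siRNA with 2500 bp, 4 after RB siRNA with gene bodies and 5000 bp, and 3 and 5 in the controls at 5 FPM or more. Shared summits beyond counting error, for inhibitor, RB siRNA and the controls, were 13.5%, 10.9% and 16.3% at a minimum of 2 FPM, 27.9%, 23.4% and 34.9% at 20, and 12.9%, 9.16% and 15.4% at gene ends only; without summits of 100 or more they were 14.3% and 10.3% in the contrasts. The median log2 ratio between the controls was 0.50 at a minimum of 2 and 0.78 at 20, and that of RB siRNA 0.50 at 20. Thinning control summits to the treated depth removed none of them, because 0 fragments pass the threshold, so it says nothing on depth. Motif settings, transcript ends and lists matched on promoter GC were not run. No paired analysis was possible because the results come from no test and each group holds 1 library. Depth limits summits under 5 FPM, where counting intervals are wide.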

Other observations

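The ribosomal RNA repeats of chromosome 21 were among the highest shared sites. Among the repeats of RNA45SN1, RNA45SN2 and RNA45SN3, that of RNA45SN2 had a summit of 531 FPM in the inhibitor control, 1921 under the inhibitor, 659 in the siRNA control and 1091 after RB siRNA. The log2 ratios were 1.86 (1.76 to 1.95) under the inhibitor and 0.73 (0.65 to 0.81) after RB siRNA, against median shifts of 0.20 and 0.45. The high inhibitor value rests on that copy: the ratio under the inhibitor was 0.71 (0.61 to 0.82) at RNA45SN3, and 0.71 (0.59 to 0.82) and 0.86 (0.74 to 0.99) at 2 summits of RNA45SN1. After RB siRNA it was 0.78 (0.70 to 0.86) at RNA45SN3 and 0.78 (0.69 to 0.86) at RNA45SN1. The controls themselves differed at these repeats, against a median shift of 0.59. The log2 ratio of the inhibitor control over the siRNA control was -0.31 (-0.41 to -0.21) at RNA45SN2 and -0.28 (-0.37 to -0.18) at RNA45SN3. At the 2 summits of RNA45SN1 it was -0.35 (-0.46 to -0.24) and -0.01 (-0.14 to 0.12), so the latter had about the same FPM in both controls. Reads from near-identical repeats cannot be assigned to 1 copy, so the contrasts are not shown to differ there. A subtelomeric summit on chromosome 5 (position 10881) was lower under the inhibitor (log2 ratio -0.80, -0.89 to -0.71).

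The tests of the following hypotheses were written before their results were seen. A shared response to loss of RB function or of its phosphorylation was expected to give a Spearman rho of at least 0.2 across gene-end summits shared by 4 libraries. The rho was -0.0921, which argues against a response in the same direction at these summits. The variation between controls could hide a smaller one. The prediction did not cover changes in opposite directions, so a response of that kind was not tested and stays open. At the 116 gene-end summits with at least 20 FPM rho was -0.22 (-0.40 to -0.03). The hypotheses that E2F target promoters move together under the inhibitor and that E2F target promoters move together after RB siRNA could not be decided, because 1 member had a shared summit in each contrast (PCNA and LIG1), too few for a median.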
